A study of Mus musculus with 479 samples.

How the data were processed

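Messenger RNA was sequenced from heart, kidney, liver and lung of wild-type and heterozygous mice of a Dchs1 and a Fat4 line, both made on a C57BL/6NTac background, per the labels. The labels' protocols name extraction with magnetic beads, poly(A) selection, strand-specific libraries and single-end sequencing, and give conflicting read lengths. The submitters' processing notes name bcl2fastq 2.17, FastQC and the genome build GRCm38. The aligner and the program that assigned reads to genes are not given in the sources used here. The authors deposited, for each line, a table of estimated counts per gene and library, of which 15.35% of values in the Dchs1 line and 15.51% in the Fat4 line were not whole, which shows that reads matching several genes were divided among them. The authors also deposited the same libraries as TPM, which are scaled to each library's total and to transcript length and keep no depth. Reads of near-identical paralogs can be divided wrongly by such an estimate, so values of single members of the Mup, Cyp2c, Ugt2b, Hsd3b, Gbp and Tgtp families are uncertain.

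Every column was matched to a labelled library by its name, 239 in the Dchs1 and 240 in the Fat4 line, and 0 columns were left unmatched. Each table listed 24475 gene identifiers, of which 24375 matched a symbol of the reference annotation (GRCm38.p6) and 100 did not. Groups were line, tissue and genotype, from the labels. No pair of libraries within a group had identical counts or differed by as little as sampling noise (lowest chi-square per gene 3.48 over genes with a mean count of at least 20). Totals of 10720364 to 32282525 reads leave a gene of 1 CPM with 10 or more reads per library. Labels number the libraries, and runs of consecutive numbers separated by gaps were taken as stretches, the only available stand-in for a batch.

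Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Each of the 8 comparisons was fitted on its own libraries, with TMM scaling, filterByExpr (minimum count 10, minimum total 15) and the quasi-likelihood (QL) F test, and p-values were adjusted by Benjamini-Hochberg (BH) over the genes tested, with a threshold of 0.05. Standard errors of log2 fold changes are the absolute fold change over the square root of F. Direction is given as the number of Het libraries on the same side of the WT median. Interactions were fitted by the same test over the lines of a tissue or the tissues of a line. Before the data were examined, 48 gene lists for pathways, complexes and cell types were fixed (718 entries, 697 matched). Lists with at least 5 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and at an estimated one, and with fry, BH over the lists of a comparison.

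The genes named were set by a rule fixed before the data were examined. It took the targeted gene, and among genes with an adjusted p under 0.05 and a mean of at least 1 CPM the 10 with the smallest p, the 6 largest rises and the 6 largest falls. It further took up to 4 members with the smallest p of each list that camera called or that had a called member, and the 8 genes at the top of each interaction test and of each ranking by variation (mean of at least 10 CPM). Genes called in all tissues of a line were ordered by size, and 2 identifiers without a symbol and those genes named from the circadian list, itself fixed beforehand, were singled out after their values were seen. Results of some genes that the rule took are not reported here. Variation between libraries is the tagwise biological coefficient of variation of edgeR within 1 group. Smaller experiments were drawn at 3 to 20 libraries per group, 8 draws per size, and WT libraries were split against each other in 7 draws per size and group.

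Alternatives fixed beforehand were DESeq2 1.42.0, its size factors within edgeR, limma on log2(TPM + 1) with genes of at least 1 TPM in 20 libraries, no filter on low counts, the number stretch as a covariate, fits without outlying libraries (median correlation with the others over 5 median absolute deviations below that of the comparison) and up to 5 surrogate variables from sva 3.50.0. Fits of the longest stretch alone and of the libraries outside it were added after the data were seen. Correlations between list scores and differences between lists were tested with 100000 permutations. On simulated counts with known changes, the test recovered 43.3% of 1.2-fold changes in Dchs1 lung and 82.1% in Fat4 lung, 92.5 to 100% of 1.5-fold changes over the 8 comparisons, and 2.8 to 5.7% of its calls in these comparisons were unchanged genes. Of 196 simulated interactions in heart it recovered 164, beside 11 unchanged genes. In each simulated comparison genes varied independently, 200 of them were changed and no number stretch was drawn. These shares therefore need not hold for the real calls.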

Results

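RNA was sequenced from heart, kidney, liver and lung of 2 mouse lines that each carry 1 modified copy of a gene for a very large cadherin. Dchs1 and Fat4 encode cell surface proteins that bind each other across neighbouring cells and act in planar cell polarity, and Fat4 is also placed upstream of the Hippo growth control pathway. Heterozygotes (Het) of each line were compared with wild types (WT) of the same line in each tissue, and the series title names the choice of group size for such experiments as its question. The 479 libraries fell into 16 groups of 30, except the Dchs1 Het liver group with 29. Totals of gene-assigned reads ran from 10720364 to 32282525 per library with a median of 18978025, and were lowest in Dchs1 lung, with medians of 14987093 in WT and 15272729 in Het. The labels give no sex, litter or batch, and do not state that the libraries of a group came from separate animals, so p-values measure the spread between libraries only. Library numbers fell into separate stretches in 7 of the 8 comparisons. These stretches stood in for an unknown batch, and counts within the longest stretch are given beside the pooled ones.

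The targeted gene was lower in heterozygotes in all 8 comparisons and lay below the WT median in every Het library. Dchs1 (identifier 233651, chromosome 7, 105752989 to 105788355, GRCm38.p6) fell from 14.5 ± 2.18 to 6.74 ± 1.22 CPM (reads scaled to library totals, mean ± SD, n = 30 and 30) in heart of the Dchs1 line. Its mean fell from 10.9 ± 1.79 to 4.96 ± 1.08 CPM in kidney, from 2.75 ± 0.695 to 1.21 ± 0.381 CPM in liver and from 18.1 ± 7.29 to 7.43 ± 2.03 CPM in lung. Fat4 (identifier 329628, chromosome 3, 38884667 to 39011992) fell in the Fat4 line from 17.02 ± 2.62 to 8.84 ± 1.70 CPM in heart, 9.42 ± 1.47 to 4.50 ± 0.800 CPM in kidney, 2.67 ± 0.712 to 1.27 ± 0.362 CPM in liver and 27.6 ± 7.11 to 13.9 ± 2.92 CPM in lung. Het levels were 41 to 46.6% of WT for Dchs1 and 47.6 to 51.9% for Fat4. The log2 fold changes (Het minus WT) lay between -1.24 ± 0.114 (SE) for Dchs1 in lung and -0.95 ± 0.0584 for Fat4 in heart, and the weakest edgeR adjusted p was 1.98e-11, in Fat4 liver with 30 of 30 Het libraries below the WT median. Het libraries that exceeded the lowest WT library numbered 1, 2, 21 and 10 in heart, kidney, liver and lung of the Dchs1 line and 1, 0, 11 and 13 in those of the Fat4 line.

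Each gene was also measured in the other line. In Dchs1 heterozygotes Fat4 rose by 0.19 ± 0.0722 on the log2 scale in kidney and fell by 0.35 ± 0.0861 in liver (adjusted p = 0.0246 and 0.000587, edgeR, the latter in 26 of 29 libraries), with -0.10 in heart and -0.26 in lung that did not pass. Among Fat4 heterozygotes Dchs1 fell by 0.20 ± 0.0513 in kidney (edgeR adjusted p = 0.00578, 25 of 30 libraries), with values of 0.02, -0.06 and -0.08 in heart, liver and lung that did not pass.

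**Figure D1:**
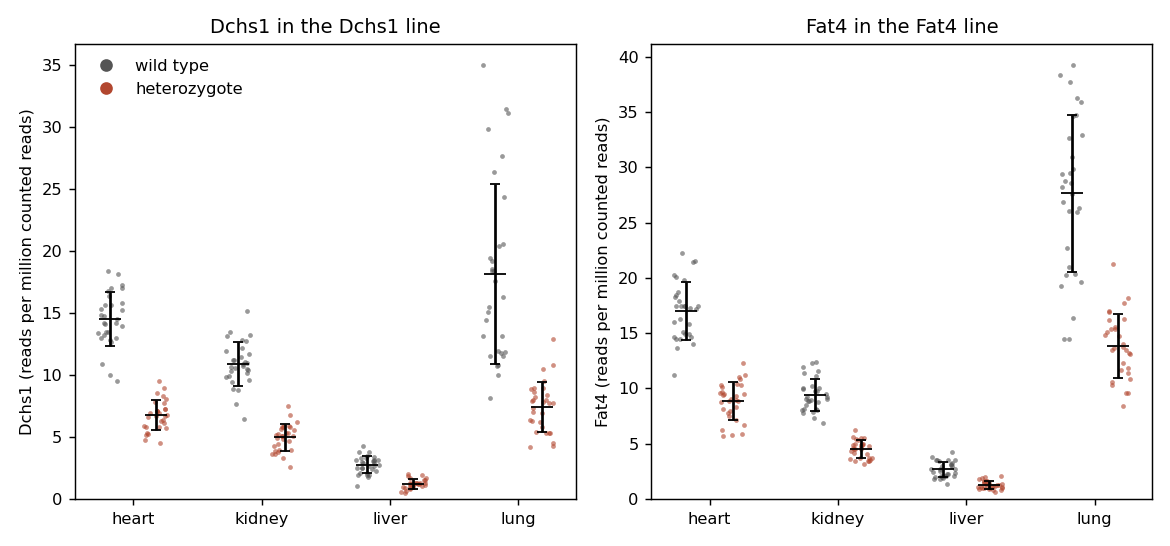
Expression of the targeted gene (CPM, vertical axis) in each library of WT and Het groups for the 4 tissues of the Dchs1 line and of the Fat4 line, with mean ± SD. Het means lie at 41 to 51.9% of the WT means.

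The number of genes called differed widely. In the Dchs1 line 6676 of 13304 tested genes changed in heart, 6671 of 14142 in kidney, 6232 of 12526 in liver and 3018 of 15069 in lung. In the Fat4 line 211 of 13213 genes changed in heart, 2393 of 14014 in kidney, 892 of 12484 in liver and 21 of 15415 in lung. These are 50.2, 47.2, 49.8 and 20% of the genes tested in Dchs1 heart, kidney, liver and lung. In the same tissues of the Fat4 line they are 1.6, 17.1, 7.1 and 0.1%. These shares join both directions. Higher and lower genes numbered 3473 and 3203 in Dchs1 heart, 3304 and 3367 in kidney, 3046 and 3186 in liver and 1447 and 1571 in lung. In the Fat4 line they numbered 128 and 83, 1290 and 1103, 454 and 438, and 17 and 4 in the same tissues. Counts of list members in 1 direction, given below, are to be read against the genes called in that direction out of those tested. Counts near that share do not set a list apart. Of the calls, 52, 49.5, 48.9 and 47.9% were higher in Dchs1 heart, kidney, liver and lung and 60.7, 53.9, 50.9 and 81% in those of the Fat4 line. These shares depend on the scaling. With limma on TPM they were 78.5 and 26.1% in Dchs1 kidney and lung and 87.1, 68.1, 13.4 and 60% in Fat4 heart, kidney, liver and lung, and in Fat4 lung 70.7% with DESeq2 and 61.1% with surrogate variables. Most changes were small. The median absolute log2 fold change of called genes was 0.21, 0.22, 0.28 and 0.31 in Dchs1 heart, kidney, liver and lung and 0.17, 0.17, 0.23 and 0.42 in the same tissues of the Fat4 line. A change of at least 1.5-fold was seen in 497, 565, 937 and 457 called genes of Dchs1 heart, kidney, liver and lung, and in 5, 32, 91 and 4 of Fat4 heart, kidney, liver and lung. In Dchs1 lung 145 of these were higher and 312 lower. The number of all calls in Dchs1 lung depended on the model. It was 4711 with the number stretch as a covariate and 6987 with surrogate variables, which gave 7548, 8210 and 7274 in heart, kidney and liver. In Fat4 lung 1637 genes had an unadjusted p under 0.05 by edgeR. Counts past a threshold follow the spread between libraries as well as the size of effects.

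**Figure D2:**
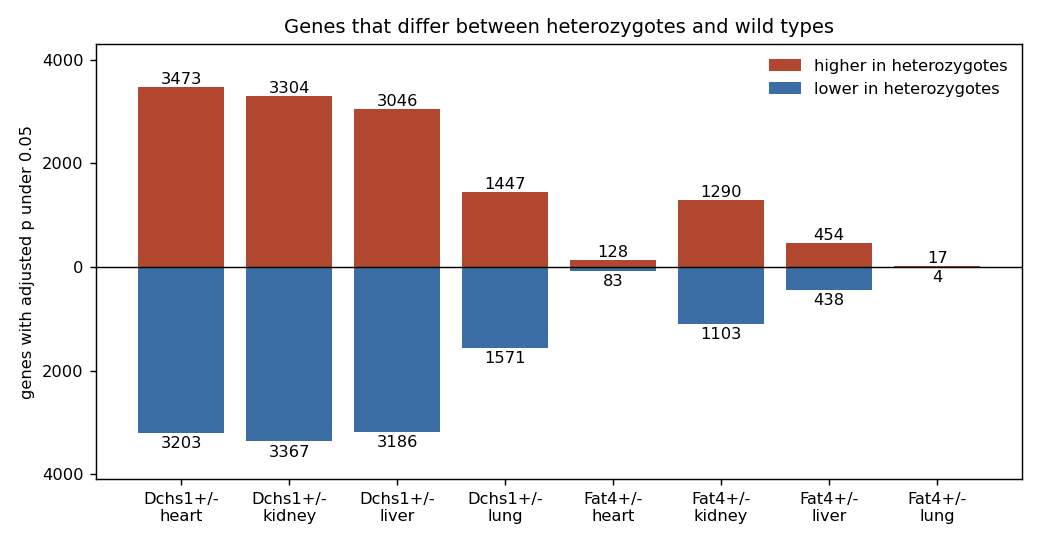
Number of genes (vertical axis) called higher (upward bars) or lower (downward bars) in heterozygotes at an adjusted p under 0.05 in the 8 comparisons. The Dchs1 line reached 6676 genes in heart and the Fat4 line at most 2393, in kidney.

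In Dchs1 heterozygous heart all 14 tested glucocorticoid response genes rose, and 13 of 15 interferon response genes and 10 of 16 ventricular cardiomyocyte genes fell. Casq1, a calcium-buffering protein of the sarcoplasmic reticulum, fell by 1.47 ± 0.11 on the log2 scale and Asph, whose products include the calcium-release protein junctin, fell by 0.58 ± 0.036 (adjusted p = 1.36e-16 and 2.94e-20, edgeR, 30 of 30 libraries each). Hmox1, which breaks down heme, rose by 2.58 ± 0.263 from 27.6 to 165 CPM, with the metallothioneins Mt2 and Mt1 up by 1.76 ± 0.172 and 1.36 ± 0.126. The sterol enzyme squalene synthase, Fdft1, rose by 0.64 ± 0.0441, and the endoplasmic reticulum chaperone Hspa5 fell by 0.71 ± 0.0564. The largest falls were those of Itgb6, an integrin subunit (-2.08 ± 0.249), the galactosyltransferase B3galt2 (-2.06 ± 0.232), the orphan receptor Gpr22 (-1.78 ± 0.154), the acetylcholinesterase anchor Colq (-1.60 ± 0.164) and the growth factor Fgf16 (-1.48 ± 0.163).

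Of the lists fixed beforehand, the glucocorticoid response list in Dchs1 heart included Fkbp5, which rose by 1.03 ± 0.138. The interferon response list had 13 lower and 2 not called (13 lower adjusted over the list alone), with Isg15 at -0.62 ± 0.0996. Antigen presentation genes of MHC class II fell in 8 of 9 cases (5 of 6 with limma on TPM), H2-Aa by 0.90 ± 0.104 and Cd74 by 0.75 ± 0.0959. Of 16 ventricular cardiomyocyte genes 10 fell and 6 were not called, among the former cardiac actin Actc1 (-0.44 ± 0.0472), phospholamban Pln (-0.34 ± 0.042) and the calcium pump Atp2a2 (-0.26 ± 0.0389). The fibroblast and matrix list had 11 of 20 lower and 2 higher (12 and 2 adjusted over the list alone), with Col6a3 at -1.11 ± 0.115. The endothelial list had 11 of 16 higher and 1 lower, with Pecam1 at 0.28 ± 0.0349 and the receptor Kdr at -0.26 ± 0.0489. Primary cilium genes were higher in 7 of 16 cases (8 higher and 1 lower adjusted over the list alone), with the transport protein Ift57 at 0.42 ± 0.0465. NRF2 targets were higher in 8 of 12 cases and lower in 3. Erythroid genes, which stand for blood in the sample, fell in 7 of 9 cases (8 adjusted over the list alone, 4 of 8 with limma on TPM), with the red cell anion exchanger Slc4a1 at -1.12 ± 0.278. YAP and TAZ targets, the readout genes of the Hippo pathway, went both ways, with 8 of 20 higher (Ccn2 by 1.08 ± 0.17) and 4 lower (9 and 5 adjusted over the list alone). Hippo components themselves had 5 of 19 higher and 4 lower (5 and 5 adjusted over the list alone).

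The heart counts came from edgeR's quasi-likelihood test, and within the longest number stretch (24 WT and 24 Het libraries) it called 6709 genes. The camera test on lists, at a preset correlation of 0.01, called 9 of 38 lists, namely those described before the YAP and TAZ list. With an estimated correlation the adjusted p was 0.554 for the glucocorticoid, interferon, MHC class II and ventricular lists, 0.815 for the fibroblast and erythroid lists, 0.651 for the endothelial list, 0.736 for NRF2 and 0.498 for the cilium list, so that 0 lists were called (1 at an unadjusted p under 0.05, and 23 by fry).

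In kidney of Dchs1 heterozygotes 14 of 15 PPAR alpha and fasting genes rose, and 15 of 16 interferon response genes and 10 of 16 proximal tubule genes fell. Ugt1a10, a glucuronosyltransferase, rose by 3.15 ± 0.258 and the fibrinogen chains Fgb, Fgg and Fga by 2.45 ± 0.253, 2.37 ± 0.238 and 2.33 ± 0.26, Fga from 51.1 to 258 CPM. The fatty acid hydroxylase Cyp4a14 rose by 1.99 ± 0.229 from 767 to 3043 CPM (edgeR adjusted p = 1.05e-10, 30 of 30 libraries). Mitochondrial arginase Arg2 rose by 1.34 ± 0.0919, while Odc1, the first enzyme of polyamine synthesis, fell by 1.44 ± 0.107 (adjusted p = 2.46e-18 and 4.5e-17, edgeR, 30 of 30 libraries each). Amacr, which prepares branched fatty acids for oxidation, fell by 1.41 ± 0.095, the chemokine Ccl28 fell by 2.23 ± 0.178, the scaffold Anks1b by 2.37 ± 0.189, the organic anion transporter Slco3a1 by 0.84 ± 0.0598 and the dipeptidase Cndp2 by 1.11 ± 0.0817.

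The list of PPAR alpha and fasting genes rose in 14 of 15 cases in Dchs1 kidney, with Cyp4a10 at 1.18 ± 0.113 and the peroxisomal enzyme Ehhadh at 0.97 ± 0.0995. Glucocorticoid response genes rose in 12 of 14 cases (13 adjusted over the list alone), the kinase Sgk1 by 0.98 ± 0.119 and the cell cycle inhibitor Cdkn1a by 1.30 ± 0.156. Interferon response genes fell in 15 of 16 cases, with Oasl2 at -0.58 ± 0.0768 and Zbp1 at -0.85 ± 0.125, and MHC class II genes in 8 of 9 (9 adjusted over the list alone). All 20 ribosomal protein genes were higher, each by little, as for Rpl5 at 0.19 ± 0.0308. In the same tissue 14 of 17 respiratory chain genes were lower (15 adjusted over the list alone, 7 of 18 with limma on TPM), with cytochrome c, Cycs, at -0.59 ± 0.0564. Proximal tubule genes fell in 10 of 16 cases, among them Miox, which breaks down inositol (-0.59 ± 0.044), the phosphate transporter Slc34a1 (-0.63 ± 0.0629) and the amino acid transporter Slc7a13 (-1.32 ± 0.12). Acute phase genes rose in 7 of 8 cases and NRF2 targets of the oxidative stress response in 9 of 12, with 2 lower, Gsta2 at 0.83 ± 0.0848 and Sod2 at -0.21 ± 0.032. Periportal hepatocyte genes, tested for other cell types, rose in 5 of 8 cases (5 higher and 1 lower adjusted over the list alone). T and NK cell markers fell in 6 of 7 cases (11 of 14 by DESeq2 and 1 of 1 by limma on TPM), with Cd4 at -0.58 ± 0.131. The sex-biased list had 5 of 9 lower, among them Cyp4a12a at -1.44 ± 0.127, and 3 higher. In the sex chromosome list there were 3 of 8 higher (2 adjusted over the list alone, 6 with limma on TPM). The YAP and TAZ list had 9 of 20 higher, Myof by 0.42 ± 0.0506, and 5 lower (9 and 6 adjusted over the list alone, 9 and 3 of 19 with limma on TPM). Hippo components had 5 of 20 higher and 2 lower (4 and 2 adjusted over the list alone and by DESeq2), while limma on TPM called 9 higher and 0 lower.

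The longest stretch of kidney libraries (23 WT and 25 Het) gave 6441 genes by edgeR. Of 43 lists camera called 11, and with an estimated correlation the adjusted p was 0.26 for the PPAR alpha and acute phase lists and 0.301 for the glucocorticoid, interferon, MHC class II, proximal tubule, periportal and NRF2 lists. The adjusted p was 0.306 for the respiratory chain, 0.345 for T and NK cells and 0.503 for ribosomal proteins, which left 0 calls (6 at an unadjusted p under 0.05, and 24 by fry).

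In Dchs1 heterozygous liver all 16 tested interferon response genes and 13 of 16 cholesterol synthesis genes fell, and 18 of 20 ribosomal protein genes rose. The bile acid and xenobiotic list went both ways, with 3 of 14 higher and 4 lower (3 and 5 adjusted over the list alone). Hsd3b5, a steroid dehydrogenase of male liver whose reads may be shared with related Hsd3b genes, fell by 4.37 ± 0.402 from 38.6 to 1.88 CPM, and carbonic anhydrase 3, Car3, fell by 3.49 ± 0.334 (adjusted p = 1.59e-13 and 5.26e-13, edgeR, 29 of 29 libraries each). The leptin receptor Lepr rose by 2.95 ± 0.408 from 36.1 to 279 CPM, and the drug-metabolising enzyme Cyp2b10 rose by 2.66 ± 0.379. Cidec, a lipid droplet protein, rose by 2.39 ± 0.356, while the desaturase Scd1 fell by 1.48 ± 0.159. The smallest p-values belonged to Glo1, which clears methylglyoxal (-0.97 ± 0.067), Syt3 (-1.91 ± 0.135) and Sdr9c7 (-1.61 ± 0.114).

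Among the interferon response genes of Dchs1 liver the regulator Irf7 fell by 1.26 ± 0.116 and Isg15 fell by 1.15 ± 0.158. Cholesterol synthesis genes fell in 13 of 16 cases with 1 higher (14 and 1 adjusted over the list alone), Msmo1 by 1.06 ± 0.131. Markers of hepatocytes near the central vein fell in 10 of 14 cases with 1 higher (11 and 1 adjusted over the list alone), with Rgn at -1.25 ± 0.118 and Cyp1a2 at -0.69 ± 0.103. Periportal markers rose in 9 of 14 cases, among them the urea cycle enzymes Arg1 (0.79 ± 0.0922) and Cps1 (0.83 ± 0.112), and fell in 3, among them Cyp2f2 (-0.45 ± 0.0612). Ribosomal protein genes rose in 18 of 20 cases (20 adjusted over the list alone), PPAR alpha genes in 12 of 15, respiratory chain genes in 11 of 16 with 1 lower (7 and 1 of 17 with limma on TPM), glucocorticoid response genes in 7 of 13, heat shock and unfolded protein genes in 8 of 15 and immediate early genes in 7 of 14, with Egr1 at 1.29 ± 0.29. MHC class II genes fell in 8 of 9 cases. The sex-biased list had 6 of 11 lower, with the transporter Slco1a1 at -1.11 ± 0.134, and 1 higher. The sex chromosome list had 3 of 8 higher, the Y-linked Ddx3y by 0.21, and 1 lower. YAP and TAZ targets had 6 of 19 higher and 3 lower, and Hippo components 4 of 19 higher, with the transcription factor Tead1 at 0.88 ± 0.208, and 2 lower. Tead1 lies within 10 Mb of Dchs1 on the same chromosome.

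Within the longest liver stretch (23 WT and 24 Het libraries) edgeR called 6160 genes. All 11 lists that camera called of 37 had an adjusted p between 0.559 and 0.578 with an estimated correlation, leaving 0 calls (2 at an unadjusted p under 0.05, and 23 by fry).

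In lung of Dchs1 heterozygotes 13 of 16 interferon response genes, 11 of 14 T and NK cell markers and 11 of 20 fibroblast and matrix genes fell. Col6a3, a chain of collagen VI, fell by 1.2 ± 0.116, the MHC class I activator Nlrc5 by 1.07 ± 0.117 and the interferon-induced GTPases Gbp4 and Gbp6 by 1.35 ± 0.18 and 1.07 ± 0.116 (edgeR adjusted p = 1.74e-11 for Col6a3, 30 of 30 libraries). Reads of the Gbp family can be shared between its members. The potassium channel Kcnt1 rose by 2.62 ± 0.272, angiotensinogen Agt by 1.60 ± 0.186, the glucocorticoid receptor cochaperone Fkbp5 by 1.57 ± 0.27, the neutrophil collagenase Mmp8 by 1.56 ± 0.221 and lipoprotein lipase Lpl by 0.75 ± 0.0792. The sodium channel gene Scn3a fell by 1.13 ± 0.117.

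Interferon response genes fell in 13 of 16 cases in Dchs1 lung (15 adjusted over the list alone), with Oas2 at -0.72 ± 0.0906. MHC class II genes fell in 8 of 10 (9 adjusted over the list alone), their activator Ciita by 1.17 ± 0.144. T and NK cell markers fell in 11 of 14 cases (12 adjusted over the list alone), Cd4 by 0.75 ± 0.115 and the granzyme Gzma by 0.92 ± 0.186. B and plasma cell markers fell in 8 of 12 (11 adjusted over the list alone), Ms4a1 by 1.01 ± 0.224. Neutrophil markers rose in 3 of 11 cases, Retnlg by 1.24 ± 0.174, and macrophage markers in 2 of 12 with 2 lower (4 lower with limma on TPM). Glucocorticoid response genes rose in 12 of 14 cases (13 adjusted over the list alone) and PPAR alpha genes in 7 of 13 (8 adjusted over the list alone), with Angptl4, an inhibitor of lipoprotein lipase, at 0.50 ± 0.0803. The fibroblast and matrix list had 11 of 20 lower, Lum by 0.93 ± 0.119 and Col3a1 by 0.81 ± 0.119, and 2 higher (11 and 3 adjusted over the list alone). Markers of other cell types moved as well, with 5 of 14 ventricular cardiomyocyte genes lower and 1 higher (6 and 1 adjusted over the list alone), 3 of 5 skeletal muscle, 3 of 14 smooth muscle and pericyte and 3 of 8 podocyte and juxtaglomerular genes lower (4, 4 and 3 adjusted over the list alone) and 3 of 12 club cell genes higher. Cholesterol synthesis genes fell in 6 of 15 cases, respiratory chain genes rose in 5 of 18 (1 with limma on TPM), and bile acid and xenobiotic genes rose in 3 of 6 with 1 lower. Of 21 genes of the Fat, Dachsous and planar polarity list 5 fell (2 of 18 with limma on TPM), the targeted Dchs1 itself being 1 of them, with Fat2 (-0.72 ± 0.111), Fat3 (-0.57 ± 0.129) and Prickle1 (-0.54 ± 0.0943). Of 21 YAP and TAZ targets 2 rose, with Ccn2 at 0.57 ± 0.0827, and 1 fell (3 with limma on TPM). Of 20 Hippo components Tead3 alone passed at 0.15 ± 0.0403 (2 by DESeq2 and 0 by limma).

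Number stretches separated the lung libraries of this line along the first principal component (42.6% of the variance). Within the longest stretch (24 WT and 24 Het) edgeR called 4623 genes against 3018 pooled, and outside it (6 and 6) it called 6. With an estimated correlation the adjusted p of the 16 lists that camera called of 44 was 0.0532 for interferon, 0.0686 for PPAR alpha, 0.128 for MHC class II, T and NK cells, podocytes and glucocorticoid response, 0.157 for the xenobiotic list and 0.203 for B cells and skeletal muscle. The adjusted p was 0.396 for cholesterol synthesis, 0.586 for smooth muscle, 0.611 for the respiratory chain, 0.211 for fibroblasts and 0.588 for the ventricular, club cell and polarity lists, the last with the target among its members, so that 0 were called (10 at an unadjusted p under 0.05, and 17 by fry).

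Fat4 heterozygous heart showed few and small changes. The membrane protein gene Lsmem1 fell by 0.32 ± 0.0463 (edgeR adjusted p = 1.07e-05, 30 of 30 libraries), and Sgk1, a kinase induced by glucocorticoids, rose by 0.40 ± 0.0765 in 26 of 30 libraries (edgeR adjusted p = 0.00382). Gclm, a subunit of the enzyme that makes the glutathione precursor, rose by 0.40 ± 0.0959 and Apold1 of the endothelium by 0.44 ± 0.107. The interferon-inducible GTPases Igtp and Tgtp1 fell by 0.57 ± 0.153 and 0.76 ± 0.205, the latter with reads that may be shared with Tgtp2, and the endoplasmic reticulum genes Sdf2l1, Pdia4 and Hsp90b1 fell by 0.45 ± 0.0987, 0.21 ± 0.045 and 0.16 ± 0.0377.

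Of 15 interferon response genes 2 fell in Fat4 heart, among them Ifi44 by 0.30 ± 0.0814, and 10 were lower when adjusted over the list alone (0 of 14 by limma on TPM and 2 by DESeq2 over all genes). Of 14 glucocorticoid response genes 1 rose, Sgk1, and 8 were higher adjusted over the list alone (5 by DESeq2 over all genes). Unfolded protein genes fell in 3 of 16 cases (6 lower and 1 higher adjusted over the list alone) and NRF2 targets rose in 1 of 12 (5 adjusted over the list alone, 2 by DESeq2 over all genes). YAP and TAZ targets gave 0 calls of 20 over all genes (10 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma) and 4 higher adjusted over the list alone. Within the longest stretch (25 WT and 23 Het) edgeR called 117 genes against 211 pooled. Camera called 8 of 38 lists, for which the adjusted p with an estimated correlation was 0.614 for the fibroblast list and 0.546 for the glucocorticoid, interferon, atrial, unfolded protein, immediate early, NRF2 and PPAR alpha lists, giving 0 calls (2 at an unadjusted p under 0.05, and 0 by fry).

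In Fat4 heterozygous kidney 15 of 16 interferon response genes and 9 of 16 endothelial genes fell, and 8 of 12 NRF2 targets rose. Cpe, a carboxypeptidase that processes peptide hormones, rose by 0.48 ± 0.0515 in 30 of 30 libraries (edgeR adjusted p = 5.6e-10). The cytochromes Cyp2b10, Cyp2a5 and Cyp2d12 rose by 1.40 ± 0.239, 0.58 ± 0.0776 and 0.53 ± 0.0744, the epithelial transcription factor Sox9 by 1.10 ± 0.201 and the antibody transporter Pigr by 0.42 ± 0.0619. The lipid-binding gene Sec14l3 fell by 0.72 ± 0.0989, and the matrix genes Col6a6, Tnn and Vcan fell by 1.01 ± 0.204, 0.64 ± 0.143 and 0.63 ± 0.146.

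Interferon response genes fell in 15 of 16 cases in Fat4 kidney (16 adjusted over the list alone), Ifit1 by 0.48 ± 0.0864. NRF2 targets rose in 8 of 12 (9 adjusted over the list alone), among them Hmox1 (0.78 ± 0.137) and the quinone reductase Nqo1 (0.34 ± 0.0643), and PPAR alpha genes in 7 of 15 (12 higher and 1 lower adjusted over the list alone). Endothelial genes fell in 9 of 16 cases (5 with limma on TPM), the angiopoietin receptor Tek by 0.20 ± 0.038, and fibroblast and matrix genes in 5 of 19 (6 adjusted over the list alone), Sparc by 0.19 ± 0.0498. Genes of the loop of Henle and distal nephron fell in 5 of 16 cases (2 with limma on TPM), with Umod at -0.28 ± 0.0938 and the salt transporter Slc12a1 at -0.35 ± 0.117, and glucocorticoid response genes rose in 5 of 14, Fkbp5 by 0.34 ± 0.0764. Smooth muscle and pericyte genes fell in 3 of 14 cases (7 adjusted over the list alone, 0 of 13 by limma on TPM and 3 of 14 by DESeq2) and macrophage markers in 2 of 10 (1 of 8 with limma on TPM). Proximal tubule genes were higher in 4 of 16 and lower in 1, and periportal hepatocyte genes higher in 4 of 8. The sex-biased list had 3 of 9 higher (4 adjusted over the list alone), MHC class II 1 of 9 lower (0 of 7 by limma and 1 of 10 by DESeq2) and the cilium list 1 of 20 higher and 2 lower (1 and 4 adjusted over the list alone, 0 and 1 of 19 with limma). YAP and TAZ targets had 2 of 20 higher and 4 lower (4 and 5 adjusted over the list alone, 2 and 1 of 19 with limma on TPM), with Rbms3 at -0.27 ± 0.0528. Hippo components had 1 of 20 higher and 2 lower, with Tead2 at -0.33 ± 0.0935. Fjx1, related to a fly kinase that tunes the binding of Fat to Dachsous, rose by 0.28 ± 0.0592.

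The longest stretch (24 WT and 24 Het) gave 2124 genes by edgeR and the libraries outside it (6 and 6) gave 2. Camera called 13 of 43 lists, and the adjusted p with an estimated correlation was 0.141 for interferon and NRF2, 0.178 for periportal, 0.421 for cilium and 0.54 for MHC class II genes and 0.458 for the endothelial, PPAR alpha, fibroblast, glucocorticoid, distal nephron, smooth muscle, macrophage and sex-biased lists, so that 0 were called (5 at an unadjusted p under 0.05, and 19 by fry).

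In Fat4 heterozygous liver 11 of 16 interferon response genes fell and 7 of 15 heat shock and unfolded protein genes rose. The transcription factor gene Tcf24 fell by 2.86 ± 0.242 from 3.77 to 0.516 CPM, and Moxd1, a monooxygenase gene, rose by 3.77 ± 0.429 from 0.149 to 2.11 CPM (adjusted p = 1.87e-13 and 3.15e-09, edgeR, 30 of 30 libraries each). Cyp2c68, Cyp2c67 and Cyp2c40 fell by 0.74 ± 0.0725, 0.69 ± 0.0769 and 1.47 ± 0.2, Ugt2b38 rose by 1.62 ± 0.16 and the urinary protein gene Mup11 by 1.05 ± 0.139 from 415 to 863 CPM. Reads of these families can be shared between near-identical members, so values of single members are uncertain. Derl3, which serves the removal of misfolded proteins, rose by 1.39 ± 0.206 and the tumour suppressor candidate Rarres1 by 1.0 ± 0.123.

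Interferon response genes fell in 11 of 16 cases in Fat4 liver (14 adjusted over the list alone), Ifit1 by 0.76 ± 0.146 and Irf7 by 0.50 ± 0.104. Heat shock and unfolded protein genes rose in 7 of 15 cases, Hspa5 by 0.48 ± 0.0718, Creld2 by 0.61 ± 0.0942 and Sdf2l1 by 0.66 ± 0.108. The sex-biased list had 5 of 10 higher (6 adjusted over the list alone, 3 with limma on TPM), with the oxysterol hydroxylase Cyp7b1 at 0.83 ± 0.119 and Mup20 at 0.47 ± 0.0798. NRF2 targets fell in 3 of 12 cases, Gsta2 by 0.65 ± 0.116 and Gclc by 0.27 ± 0.0734. Glucocorticoid response genes had 1 of 13 higher, Ddit4 at 1.03 ± 0.29, with 3 higher and 1 lower adjusted over the list alone (2 of 14 higher by DESeq2, 0 higher and 1 lower of 13 by limma on TPM). Of 19 YAP and TAZ targets 1 rose and 2 fell. Within the longest stretch (22 WT and 27 Het) edgeR called 732 genes, and without the 5 libraries that correlated least with the others it called 1221 against 892. Camera called 7 of 37 lists, and for the interferon, unfolded protein, sex-biased and NRF2 lists the adjusted p was 0.186 with an estimated correlation and for the ribosomal protein, PPAR alpha and MHC class II lists 0.705, leaving 0 calls (4 at an unadjusted p under 0.05, and 5 by fry).

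In Fat4 heterozygous lung 17 genes were higher and 4 lower, the former with 2 identifiers that have no gene symbol. Sgk1 rose by 0.33 ± 0.0565 in 28 of 30 libraries and endothelin 1, Edn1, a constrictor of vessels, by 0.53 ± 0.096 in 26 of 30 (adjusted p = 0.000623 and 0.00239, edgeR). The hydroxysteroid dehydrogenase Akr1c14 rose by 0.49 ± 0.097, the secreted protein genes C1qtnf3 and Angptl7 by 0.38 ± 0.0716 and 0.46 ± 0.102, and the pericyte regulator Rgs5 by 0.32 ± 0.0711. The genes that fell besides Fat4 were the esterase Ces2b (-0.47 ± 0.109), the interferon-inducible nucleotide kinase Cmpk2 (-0.26 ± 0.0598) and Pgghg (-0.12 ± 0.0264).

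Interferon response genes gave 0 calls of 16 over all genes in Fat4 lung (16 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma), while 16 were lower adjusted over the list alone, with a median log2 fold change of -0.21. Of 14 glucocorticoid response genes 1 rose, Sgk1, and 5 were higher adjusted over the list alone. The YAP and TAZ list gave 0 of 21 (3 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma). All libraries of this comparison lay in 1 number stretch. Of the 5 of 44 lists camera called, the adjusted p with an estimated correlation was 0.143 for interferon, 0.378 for glucocorticoid response, 0.629 for neutrophils and 0.954 for cholesterol synthesis and for the polarity list, which holds the target, giving 0 calls (3 at an unadjusted p under 0.05, and 1 by fry).

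**Figure D3:**
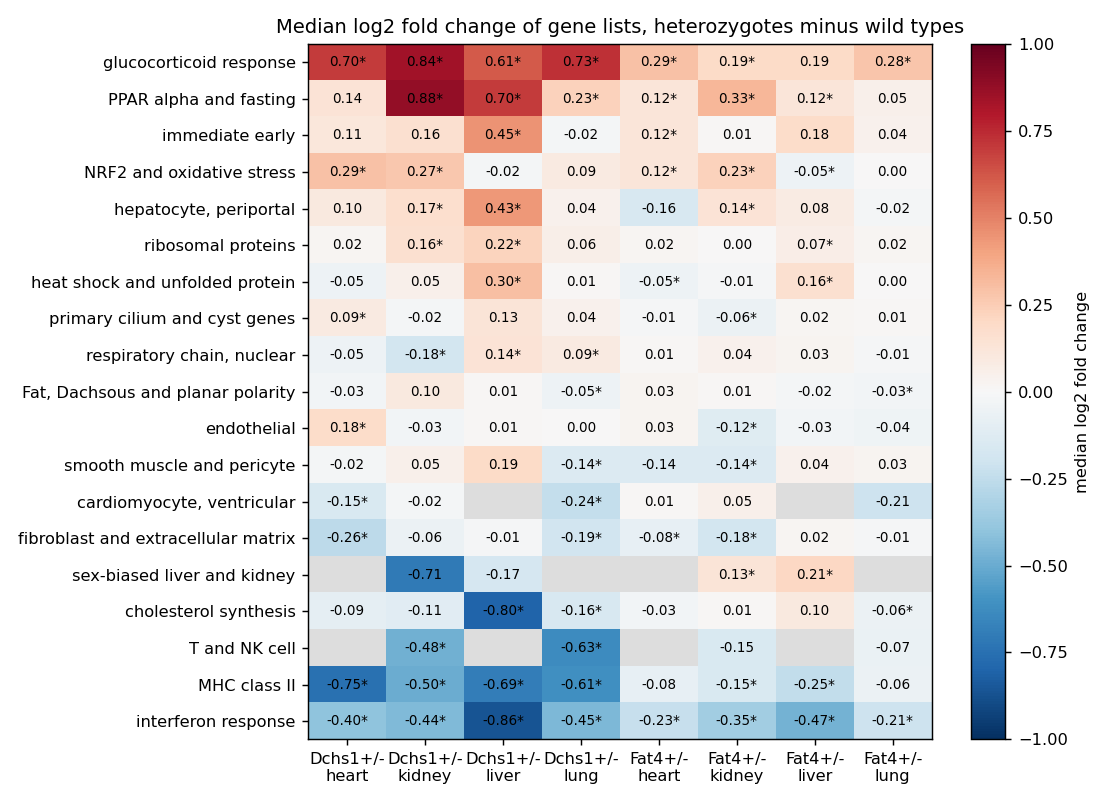
Median log2 fold change (Het minus WT, colour) of the members of 19 gene lists in the 8 comparisons, with an asterisk where camera at the preset correlation gave an adjusted p under 0.05, of which 0 held with an estimated correlation, and grey where fewer than 5 members were tested. Medians of the interferon list lie between -0.86 and -0.21 and those of the glucocorticoid list between 0.19 and 0.84.

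The lines shared more genes of the same direction in each tissue than independent lists would. In liver 306 genes were higher and 346 lower in both lines (109.3 and 111.9 by chance, one-sided Fisher's exact p = 1.16e-88 and 1.44e-126), with 44 in opposite directions (221.4 by chance). Heart shared 107 higher and 68 lower genes (33.1 and 19.9 by chance, p = 2.63e-43 and 4.6e-29), kidney 524 and 363 (300.4 and 263.5, p = 1.94e-48 and 8.66e-13) and lung 11 and 3 (1.4 and 0.3, p = 5.81e-09 and 0.00113). Genes called in opposite directions numbered 2 in heart, 439 in kidney and 0 in lung (52.2, 565.1 and 1.9 by chance). Fold changes of the lines correlated across genes with r = 0.54, 0.26, 0.51 and 0.54 in heart, kidney, liver and lung. Genes are not independent replicates. The lines have separate WT groups.

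Between tissues of the Dchs1 line, 183 genes were higher and 167 lower in all 4 (18.3 and 11.7 by chance) of 11448 tested throughout. The glucocorticoid-induced Fkbp5 rose by 1.03, 0.75, 0.87 and 1.57 in heart, kidney, liver and lung, and Cdkn1a by 0.75, 1.30, 0.88 and 0.86. Lyve1, a receptor of lymphatic vessels whose gene lies within 10 Mb of Dchs1 on the same chromosome, rose by 0.70, 0.80, 0.74 and 0.78. The genes lower throughout included the MHC class II activator Ciita (-0.82, -0.67, -0.80 and -1.17), H2-Ab1 (-0.94, -0.59, -0.83 and -0.75) and the nucleic acid sensor Zbp1 (-0.73, -0.85, -1.31 and -0.75). Of the Fat4 line's 11384 genes tested throughout, Fat4 was the 1 gene called in the same direction in all 4 tissues. Tissues of a line may come from the same animals, which the labels do not state, so chance values for independent lists can be too low.

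The difference in genotype effect between the lines was tested as an interaction. It passed for 3475 of 13623 genes in heart, 4802 of 14353 in kidney, 3034 of 12855 in liver and 775 of 15496 in lung. In heart Casq1 fell by 1.47 in the Dchs1 line and stood at -0.22 in the Fat4 line, and Jph2, which joins the calcium stores to the cell membrane, at -0.67 and -0.08 (adjusted p of the difference 3.76e-10 and 2.05e-09, edgeR). In kidney Slco3a1 stood at -0.84 and 0.09, in liver the aldehyde oxidase Aox3 at -2.30 and -0.11, and in lung Col6a3 at -1.2 and -0.18. Between the tissues of the Dchs1 line 8603 of 16477 genes differed in their effect, with Odc1 first (0.01 in heart, -1.44 in kidney, 0.50 in liver and 0.13 in lung, edgeR adjusted p = 1.92e-50). In the Fat4 line 1172 of 16441 differed, led by Tcf24, and the chaperone cofactor Sdf2l1 stood at -0.45, -0.23, 0.66 and -0.16 in heart, kidney, liver and lung (edgeR adjusted p = 7.31e-14). Both tissue tests treated libraries of different tissues as independent, although they may come from the same animals.

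Genes within 10 Mb of Dchs1 were called in 81 of 147 cases in heart, 78 of 153 in kidney, 67 of 139 in liver and 42 of 167 in lung, and those near Fat4 in 1 of 51, 10 of 56, 1 of 46 and 1 of 62. In none of the 8 comparisons did the share among neighbours pass a test against that of the other genes (two-sided Fisher's exact test, adjusted p 0.396 to 0.859 over the 8).

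The median biological coefficient of variation (BCV) over genes was 0.109, 0.125, 0.158 and 0.197 in WT heart, kidney, liver and lung of the Dchs1 line and 0.097, 0.106, 0.132 and 0.116 in the Fat4 line, and Het groups ranged from 0.101 to 0.2. These groups pooled number stretches except in Fat4 lung, and in Dchs1 lung the stretch correlated at 0.92 with the first principal component over all libraries, which held 42.6% of the variance. In WT heart the most variable genes included Pck1 and Car3, which adipose tissue expresses (BCV 1.34 and 1.26 in the Dchs1 line), and the atrial light chain Myl7 (0.83), which ran from 1.79 to 175 CPM. In WT liver of the Dchs1 line the acute phase genes Saa2 and Saa1 reached 1.94 and 1.65, Saa2 running from 5.4 to 5340 CPM, and the leptin receptor Lepr reached 1.21. Xkrx ran from 0.946 to 2550 CPM in WT lung of the Dchs1 line. In WT kidney Cyp4a14 and Fga, which also separated the genotypes there, had 0.76 and 0.8.

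Smaller experiments were drawn from the same libraries to ask how many of the full calls they find. With 3 libraries per group the median share found over 8 draws was 0, 1.3, 0.7 and 0% in Dchs1 heart, kidney, liver and lung, and Dchs1 itself was called in 4, 4, 0 and 0 of 8 draws. With 10 per group the share was 44.6, 33.4, 42.6 and 15.8%, Dchs1 was called in 8 of 8 draws in each tissue, and single draws in heart ranged from 27.4 to 58.6%. With 20 per group it was 79.8, 72.1, 76.7 and 53.6%. In the Fat4 line 10 per group found 0.9, 0.4, 2.9 and 14.3% of the calls in heart, kidney, liver and lung, and 20 per group 6.2, 52.2, 35.7 and 35.7%, while Fat4 itself was called at 10 per group in 8, 8, 8 and 7 of 8 draws. In Fat4 heart and lung the median draw of 10 per group called 3 genes, so the share found there can consist of Fat4 and the identifiers without a symbol that were read almost only in heterozygotes. Of the genes called at 10 per group, 3.4, 6.1, 5.9 and 13.8% were not among the full calls of Dchs1 heart, kidney, liver and lung. In the same tissues of the Fat4 line it was 90.1, 14.3, 14.3 and 16.1%, and in Fat4 heart 467 of the 487 calls pooled over draws came from 1 draw. Larger draws did not lower this share throughout. At 20 per group it was 5, 3.7, 4 and 11.8% in the Dchs1 line and 69.1, 25.4, 9.3 and 87.6% in the Fat4 line, where 1 draw gave 788 of 1205 calls in heart and 456 of 531 in lung. Subset and full calls share libraries. At 3 per group the fold change of genes called in both was 1.35, 1.16, 1.45 and 1.95 times the full one in the median in Dchs1 heart, kidney, liver and lung, where 23 of the 24 pooled calls in lung came from 1 draw. In the Fat4 line these draws pooled 9 calls in kidney and 22 in lung, and 1 draw gave 620 of 629 in heart and 672 of 683 in liver, so no ratio is given. When WT libraries were tested against WT libraries of the same group, 7 of 56 draws of 3 against 3 called any gene. Single draws called 2980 genes in Dchs1 lung at 3 per group, 3049 in Dchs1 kidney at 5, and 1030 in Dchs1 kidney and 514 in Dchs1 lung at 10, while the most in the other 6 comparisons was 165, in Fat4 heart at 3 per group. In Dchs1 kidney the number stretch correlated at 0.69 with the second principal component. At 5, 10 and 15 per group 1, 2 and 1 of 56 draws called any gene.

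**Figure D4:**
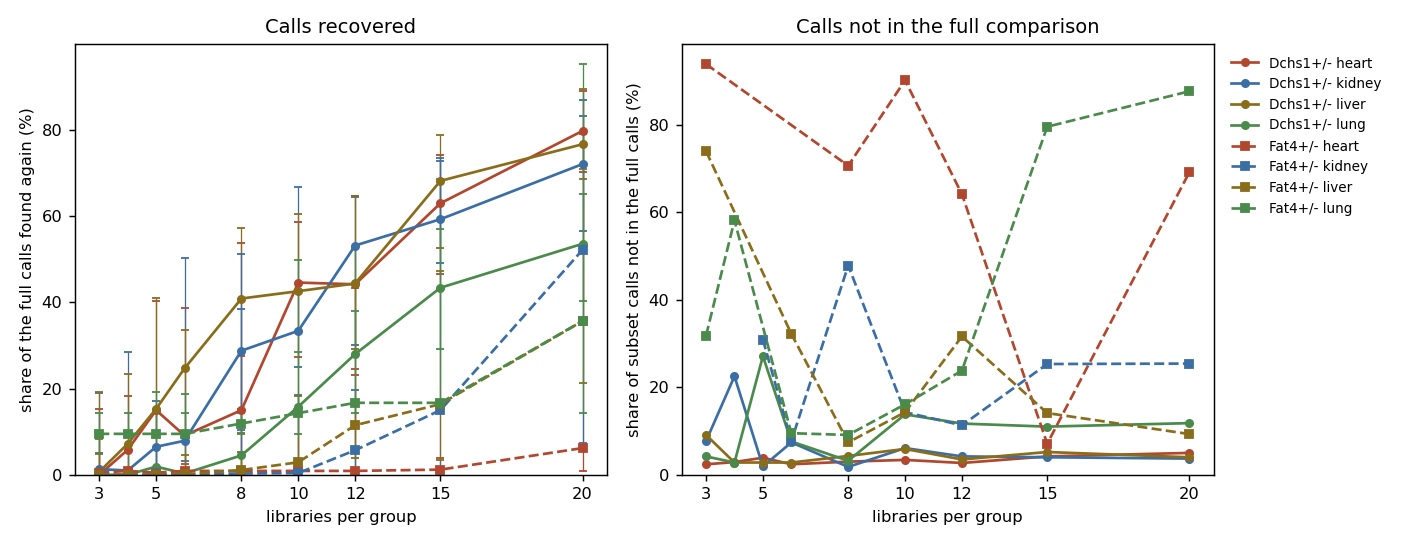
Left, percent of the full calls found again (vertical axis) against libraries per group (horizontal axis), as the median of 8 draws with the lowest and highest. Right, percent of subset calls that are not full calls, shown where the pooled draws held at least 20 calls. At 10 per group Dchs1 heart stands at 44.6% and Fat4 kidney at 0.4% on the left.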

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

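The interaction tests were planned, the tests of collection time and animal state were set after the data had been examined but before their own results were seen (for collection time, after the counts of called circadian genes), and the tests of library number, of the origin of the unmatched identifiers and of carry-over were chosen after their results were seen. Genotype effects differed between the Dchs1 and Fat4 lines for 3475 genes in heart, 4802 in kidney, 3034 in liver and 775 in lung, and between the tissues of a line for 8603 genes in the Dchs1 line and 1172 in the Fat4 line (edgeR QL interaction, BH). When genotypes were reassigned within each line and tissue, only the real assignment of the 40 drawn, 1 of 40, reached these numbers in each tissue, the highest others being 17 in heart, 1 in kidney, 1012 in liver and 2 in lung. For the tissue tests it was 1 of 25, with highest others of 2304 in the Dchs1 and 123 in the Fat4 line. This argues against chance for the 6 counts, but so few draws cannot exclude it. Genotypes were reassigned separately in each tissue, which leaves aside that tissues of a line may come from the same animals.

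In heart, besides the targets, the difference of log2 fold changes, Fat4 line minus Dchs1 line, was 0.46 for the autophagy regulator Trp53inp2, 0.37 for the Wnt receptor partner Kremen1, 1.26 for the calcium buffer Casq1, 0.60 for Jph2, 0.39 for the membrane repair gene Dysf and 0.44 for Asph, all lower in Dchs1 heterozygotes. In heart the targets differed by 1.13 (Dchs1) and -0.84 (Fat4). In kidney the differences were 0.92 for Slco3a1, 1.93 for the protease Tmprss9, 0.69 for Acsm2, 0.86 for the esterase Ces1e and 1.69 for the acetyltransferase Nat8f5, with 0.98 for Dchs1 and -1.27 for Fat4. In liver they were 0.78 for Rassf3, 1.43 for Sdr9c7, 0.60 for the calcium sensor Stim1 (within 10 Mb of Dchs1), 2.2 for Aox3 and 1.65 for Saa4, and in the other direction -0.51 for the amino acid transporter chain Slc3a2 and -0.42 for the lysosomal enzyme Hexa. In lung they were 1.17 for Dchs1, 1.2 for Scn3b, 1.89 for carbonic anhydrase 12, Car12 (not tested by genotype in Dchs1 lung alone, where it failed the count filter), 1.03 for Col6a3, 0.83 for the tubulin Tubb2b and 0.79 for Ifi203, and -0.88 for the protease inhibitor Spink5 and -0.62 for Lpl.

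The breadth of the Dchs1 response, which reached 6676 genes in heart, is the pattern most in need of an account. The longest stretch alone held at least 96.6% as many calls as the pooled test in each of the 4 tissues, and 153.2% in lung. This argues against differences between stretches as the source. Genotypes were near balance over the stretches (in heart 24 WT and 24 Het within the longest and 6 and 6 outside it), so the design largely set this outcome. Batches within a stretch were not tested. A difference in the time of collection stays open. The mean log2 fold change of clock output and repressor genes minus that of Arntl, Npas2, Clock and Cry1 was negative in all 4 tissues. It was at least 0.5 in size in 1 of the 4 tissues, kidney (-1.23, against -0.11 in heart, -0.46 in liver and -0.38 in lung). The tissues were not compared on the same genes. Ciart was not tested in kidney, which left 6 output and repressor genes there against 7 elsewhere. In liver Ciart rose by 1.01 while the others of these genes had negative values, which made the liver difference smaller in size. A state of the animals that also varies among wild types, such as feeding or stress, and the genotype itself cannot be told apart, because 0 of the 4 tissues gave a correlation across genes of at least 0.5 in size with the main axis of WT libraries of the Fat4 line (-0.43, 0.11, 0.37 and 0.25 in heart, kidney, liver and lung) but other such states need not show on that axis. Fold changes of the Fat4 line gave r of -0.56, -0.29, -0.39 and 0.08 with the WT axis of the Dchs1 line, where heart passed 0.5 in size, while those of the Dchs1 line gave -0.40, 0.17, -0.78 and 0.06 with the axis of their own controls, which decides nothing, because shared controls alone can give such values and none was simulated without an effect. The sign of such an axis is arbitrary, so only the size of these r can be read. In Dchs1 lung the number stretch correlated at 0.92 with the first principal component over all libraries. The lung axis of that line may therefore hold the stretch, and its values cannot speak to a state of the animals.

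Reads of an identifier that matched no gene symbol were present in 238 of the 239 Het libraries of both lines and in 3 of 240 WT libraries with 1 read each, and those of another such identifier in 201 Het libraries and 1 WT library. Mean CPM of the former in heterozygotes was 1.10, 1.03, 0.197 and 1.93 in heart, kidney, liver and lung of the Dchs1 line and 3.34, 3.28, 0.369 and 17.4 in the Fat4 line. Carry-over between libraries is argued against by a WT level of 0.0245% of that in heterozygotes. A sequence carried by both modified alleles and read out with the targeted gene may be the source. The level tended to be higher where that of the target in WT was higher over the 8 comparisons (rho 0.79, exact permutation p 0.0279, and r 0.79, exact permutation p 0.00811). Without the 2 farthest comparisons r was 0.51 and rho 0.54. The 8 comparisons are 4 tissues of 2 lines, and tissues of a line may come from the same animals, so these p can be too small. Which sequence the identifiers stand for is not given in the sources used here.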

How the results depend on the processing

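The alternatives were planned, except the fits within and outside the longest number stretch, which were chosen after the data were seen. No paired analysis was possible because replicate numbers follow the order of accession and pair nothing. Of 3496 values of named genes under other settings, 3137 kept direction and side of the threshold, 309 were weaker, 35 stronger and 15 reversed, all 15 outside the longest stretch, where 171 of 404 stayed and 218 were weaker. Of 60 target values 58 stayed, of 63 counts of calls 43 lay within 1.5 times the main one, of 63 counts of 1.5-fold calls 37, and of 128 values of interaction genes 128 stayed. The libraries outside the stretch numbered 3 to 8 per group, and genes too shallow for the count filter were not tested. No scaling moved the median of all genes by over 0.1. The median farthest from none was 0.082, with limma on TPM in Dchs1 kidney. There lower calls went from 3367 to 1358. Of 6139 main calls tested there 4401 were called again and 5949 kept their sign, so many small changes depend on the scaling. limma gave no target value in Dchs1 liver, Fat4 kidney and Fat4 liver, where TPM fell under its filter. On its log2(TPM + 1) scale, which understates changes of low genes, the target stood at -0.61, -0.55 and -0.81 in Dchs1 heart, kidney and lung, against -1.10, -1.19 and -1.24 by edgeR, and at -0.48 against -0.95 in Fat4 heart. For the values that follow the cause was not tested, except where fewer libraries or genes entered.

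With DESeq2, calls of at least 1.5-fold rose to 846, 928 and 1415 in Dchs1 heart, kidney and liver, 57 in Fat4 kidney and 7 in Fat4 lung, and all calls to 337 in Fat4 heart and 58 in Fat4 lung. With limma on TPM, 1.5-fold calls were 212, 288, 537 and 246 in Dchs1 heart, kidney, liver and lung and 2, 13 and 46 in Fat4 heart, kidney and liver, and all calls 132, 1453 and 10 in Fat4 heart, kidney and lung. Without a filter on low counts, 1.5-fold calls were 938, 1116, 1540 and 777 in Dchs1 heart, kidney, liver and lung, 113 in Fat4 kidney and 7 in Fat4 lung, and Fat4 heart had 95 calls.

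With the number stretch as a covariate, Dchs1 lung had 4711 calls, Fat4 heart 346 and the line by genotype test in lung 1335. Within the longest stretch Dchs1 lung had 4623 calls and Fat4 heart 117, 3 of them of at least 1.5-fold. Surrogate variables gave 6987 calls in Dchs1 lung, 1368 in Fat4 liver and 36 in Fat4 lung, with 3 and 18 of at least 1.5-fold in Fat4 heart and kidney. Outside the longest stretch calls numbered 1067, 1511, 1987 and 6 in Dchs1 heart, kidney, liver and lung, 2, 2 and 0 in Fat4 heart, kidney and liver (462 in Fat4 liver at an unadjusted p under 0.05, no other tool run there), and 1.5-fold calls 243 and 6 in Dchs1 heart and lung and 2, 2 and 0 in Fat4 heart, kidney and liver. There Dchs1 in Dchs1 lung stood at -0.70 (edgeR adjusted p = 0.29) and Fat4 in Fat4 liver at -1.45 (edgeR adjusted p = 0.821), both no longer past the threshold. Signs turned there for Ptprb (-0.01) in Dchs1 heart, Smtn (0.05) and Mylk (0.00) in Dchs1 lung, Pdk4 (-0.09) in Fat4 heart, Col1a2 (0.03), Mmp2 (0.07), H2-Eb1 (0.09), H2-Aa (0.07), H2-Ob (0.25), C1qb (0.10) and C1qc (0.06) in Fat4 kidney, and Rps9 (-0.02), Cyp4a10 (-0.07), Pdk4 (-0.90) and Nqo1 (0.25) in Fat4 liver.

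Without 5 outlying libraries in each, 2 WT and 3 Het in Dchs1 lung and 3 WT and 2 Het in Fat4 liver, calls were 3769 and 1221. Among other moves of list counts by over 1.5 times, limma on TPM called 1 gene in place of 2 for lower NRF2 targets in Dchs1 kidney and for higher fibroblast genes in Dchs1 heart and lung. It called 1 neutrophil and 1 glucocorticoid gene lower in Dchs1 lung and 1 interferon gene higher in Dchs1 kidney, directions in which edgeR made no call. DESeq2 called 2 in place of 1 for higher sex-biased genes in Dchs1 liver and lower xenobiotic genes in Dchs1 lung. With an estimated correlation 0 gene lists were called in each of the 8 comparisons. In subsets of 10 per group, the share found of genes changed at least 1.5-fold was 73.2, 72.8, 73.7 and 38.4% in Dchs1 heart, kidney, liver and lung and 12.5 and 14.8% in Fat4 kidney and liver. The share of subset calls at 5 per group that a reference without the subset did not call was 9.9, 4.8, 9.2 and 44.1% in Dchs1 heart, kidney, liver and lung and 69.9 and 31.2% in Fat4 kidney and liver. At that size 1 draw gave 965 of the 1626 pooled calls in Dchs1 lung and 226 of 395 in Fat4 kidney, and Fat4 liver pooled 16 calls.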

Other observations

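The test of leukocyte share was chosen after its result was seen, that of animal state was set after the data had been examined but before its own result was seen, and the counts over splits were planned. Genes of the circadian clock went both ways in kidney of Dchs1 heterozygotes, with 6 of 15 higher and 6 lower. The clock output genes Dbp, Tef and Hlf fell by 1.68 ± 0.19, 0.53 ± 0.084 and 0.49 ± 0.096, the period gene Per3 by 0.65 ± 0.0919 and the repressors Nr1d1 and Nr1d2 by 0.66 ± 0.102 and 0.40 ± 0.0849, while Cry1, Npas2 and Arntl rose by 0.89 ± 0.103, 0.59 ± 0.116 and, for Arntl within 10 Mb of Dchs1, 0.40 ± 0.0619 (weakest edgeR adjusted p = 8.16e-05, that of Nr1d2 in 26 of 30 libraries). Clock itself stood at 0.09 and was not called (edgeR adjusted p = 0.111). In liver of the same line the list had 3 of 15 higher and 8 lower, where Per3, Tef and Hlf fell by 0.85 ± 0.189, 0.64 ± 0.111 and 0.48 ± 0.0994 and Npas2 rose by 0.52 ± 0.113, but Ciart, a clock repressor, rose by 1.01 ± 0.277 and Cry1 fell by 0.18 ± 0.0587. Also in liver, Nr1d1 and Nr1d2 fell by 0.785 ± 0.222 and 0.371 ± 0.103 and Arntl rose by 0.185 ± 0.0699. In heart the list had 8 of 16 higher and 3 lower, with Tef at 0.48 ± 0.0622 and Nr1d1 at -0.56 ± 0.106, and in lung 8 of 16 higher and 1 lower (2 and 2 by limma on TPM), with Cry1 at 0.50 ± 0.0992 and Nr1d1 at -0.31 ± 0.0912. Nr1d1 was thus called lower, and Npas2 and Arntl higher, in every tissue of the Dchs1 line, while Tef fell in kidney and liver and rose in heart and lung. In the Fat4 line 3 of 15 were higher and 1 lower in kidney, where Cry1 and Npas2 rose by 0.31 ± 0.0963 and 0.33 ± 0.112 and Nr1d1 fell by 0.31 ± 0.0911 (adjusted p = 0.0212, 0.035 and 0.0151, edgeR, in 22, 19 and 22 of 30 libraries). Nr1d1 alone fell in Fat4 heart, by 0.35 ± 0.086, 1 of 16 was higher in liver, and 0 of 16 passed in lung by edgeR (5 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma).

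Genes that differ between the J and N stocks of C57BL/6 went both ways, with 2 of 6 higher and 2 lower in Dchs1 heart, 1 and 3 in kidney, 1 and 2 in liver and 1 of 8 higher in lung, and 1 of 6 higher and 1 lower in Fat4 kidney and in Fat4 liver. Entpd4 fell by 0.74 ± 0.0568 in Dchs1 kidney (edgeR adjusted p = 1.39e-16, 30 of 30 libraries), and Nlrp12 rose by 0.47 ± 0.127 in Dchs1 liver and 0.30 ± 0.0944 in Fat4 liver (adjusted p = 0.00147 in 27 of 29 and 0.041 in 24 of 30 libraries, edgeR). In Fat4 heart and lung edgeR called 0 of them (3 of 6 and 2 of 8 at an unadjusted p under 0.05, 0 and 1 by DESeq2, 0 and 0 by limma). Genes of the cell cycle, the proliferation list, had 3 of 14 higher in Dchs1 heart and kidney, with 1 lower in kidney, 1 of 10 higher in liver and 2 of 16 lower in lung. Adipocyte genes had 3 of 11 higher in Dchs1 heart, 5 of 13 higher with 1 lower in Dchs1 kidney, 3 of 7 higher and 3 lower in liver and 2 of 12 higher and 1 lower in lung. Of 38 lists in Dchs1 heart, those that varied most between WT libraries were the adipocyte, erythroid and atrial lists, with a median BCV of 1.12, 0.70 and 0.61.

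The median log2 fold change lay between 0.19 and 0.84 for the glucocorticoid list and between -0.86 and -0.21 for the interferon list over the 8 comparisons, but camera with an estimated correlation called neither in any of them (lowest adjusted p = 0.0532), and 1 of 14, 1 of 13 and 1 of 14 glucocorticoid genes passed edgeR in Fat4 heart, liver and lung. An even loss of all leukocytes is argued against as the whole cause in Dchs1 lung. The neutrophil list stood 0.95 above the T and NK cell list there (medians 0.33 and -0.63, permutation p 0.00011, BH 0.00048 over 6 pairs), while such a loss would lower both. Genes of a list can vary together, so this p can be too small. A lower share of lymphocytes stays open, with the B and plasma cell list at -0.73 and the macrophage list at -0.06. A state of the animals, such as stress before collection, stays open beside the genotype, since list scores of WT libraries correlated at r of -0.3 or below in 3 of 8 groups (-0.55 to 0.18 over the 8, 1 of them with BH under 0.05, adjusted over 16 relations), and in each of these 3 the relation rests on the 2 farthest libraries, without which r went from -0.33 to -0.10 in Dchs1 heart, -0.37 to 0.09 in Dchs1 liver and -0.55 to -0.24 in Dchs1 lung. Het libraries gave -0.70 to -0.12, at -0.3 or below in 7 of 8 groups and with BH under 0.05 in 3, namely Dchs1 kidney (r -0.48, permutation p 0.00776, BH 0.0376; rho -0.47, p 0.00872, BH 0.0487; -0.45 without the 2 farthest libraries and -0.49 within the longest stretch), Fat4 liver (r -0.46, permutation p 0.00941, BH 0.0376; rho -0.47, p 0.00913, BH 0.0487; -0.45 and -0.44) and Dchs1 lung (r -0.70, permutation p 2e-05, BH 0.00032; rho -0.72, p 3e-05, BH 0.00048; -0.74 without the 2 farthest libraries, -0.71 within and -0.49 outside the longest stretch). In the 3 WT groups rho was -0.18, 0.04 and -0.32 (permutation p 0.344, 0.824 and 0.088) and the permutation p of r 0.0755, 0.0516 and 0.00416 (BH 0.121, 0.111 and 0.0333), while r was -0.29, -0.45 and -0.61 within the longest stretch and -0.74, 0.57 and -0.37 in the 6, 7 and 6 libraries outside it.

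When the libraries of each comparison were split at random into groups of the same sizes, no other split drawn called as many genes. This argues against chance, but 100 splits cannot exclude it. The splits also treat libraries as exchangeable, which the labels do not settle. The real split was 1 of the 100 splits to reach its number in each comparison, with 6676 against at most 1099 in Dchs1 heart, 6671 against 516 in kidney, 6232 against 12 in liver and 3018 against 1 in lung, and 211 against 55, 2393 against 321, 892 against 527 and 21 against 2 in Fat4 heart, kidney, liver and lung. For genes of at least 1.5-fold it was 1 of the 100 in 6 comparisons, with 497 against 50, 565 against 49, 937 against 10 and 457 against 1 in Dchs1 heart, kidney, liver and lung and 32 against 6 and 91 against 20 in Fat4 kidney and liver. In Fat4 heart it was 2 of the 100, with 5 against 10. In Fat4 lung it was also 1 of the 100, with 4 against 0, but 3 of these 4 are Fat4 and the 2 identifiers without a symbol, which part the genotypes by themselves, so this count decides nothing on a response beyond the modified allele. The number of lists camera called was not beyond chance: 16, 11, 7 and 8 of the 100 splits called as many in Dchs1 heart, kidney, liver and lung (9 against at most 14, 11 against 15, 11 against 14 and 16 against 20) and 29, 8, 35 and 95 in Fat4 heart, kidney, liver and lung (8 against 16, 13 against 15, 7 against 13 and 5 against 23).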
